A study of Bos taurus with 90 samples.

How the data were processed

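Tissue from ileal loops of pre-weaned calves was profiled by mRNA sequencing and small RNA sequencing. A loop is a length of ileum closed off in the living animal, and each held 0, 0.5, 5, 50 or 500 mg of allicin, an antimicrobial sulphur compound of garlic, for 1, 3 or 12 days. Each assay gave 45 libraries, 3 for each of the 15 combinations of dose and day. Groups, doses, days and replicate numbers came from the sample titles. The labels do not say which loops shared a calf, so p-values measure the spread between these samples, part of which may be within one animal.

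Per the labels' protocols, RNA was extracted with Trizol and libraries were made with TruSeq kits. Per the submitters' processing notes, CASAVA 1.8, TopHat2 2.0.10, HTSeq (version not given in the sources used here) and the UMD3.1 genome build were used; the notes do not say which tool served which assay. The deposited values of both assays are CPM as the authors made them, the reads of a feature scaled to a common total, and each file sums to that total. The values stay whole multiples of the worth of 1 read in the mRNA files, so that reads could be recovered: 100% of the values above 0 came out whole within 0.05 of a read in each library. The small RNA values are multiples of a hundredth of a read, as arises when a read is shared between similar miRNAs. Between 77.91% and 87.56% of their values above 0 were whole reads within the same tolerance. The worth of 1 read was taken as the largest step tried that made at least 70% of a small RNA library's values whole, so that a share of at least 70% was set by the rule. Recovered depth was 9133789 to 16145200 reads in the mRNA libraries (median 11586148) and 480657 to 2097846 in the small RNA libraries (median 937847) except 1: that of 50 mg day 3 replicate 3 held 30398 reads, so that 1 read there was worth 32.9 CPM. No replicate pair agreed within sampling noise: the chi-square of the reads per degree of freedom was at least 5.509 for miRNA and 6.419 for mRNA.

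The tests first fixed assumed counts (edgeR's quasi-likelihood test). As the values are CPM, the reported tests are limma 3.58.1 (R 4.3.3) on log2 of TMM-scaled CPM plus a pseudocount of 0.5 for mRNA and 1 for miRNA, with trended and robust empirical Bayes variances. The pseudocounts and the filters were chosen once the unit was known and exploratory fits had been run. Fold changes are on that scale, which understates the change of low features. Features with at least 1 CPM (mRNA) or 10 CPM (miRNA) in 3 libraries were tested, 15107 genes of 24616 and 267 miRNAs of 793. One model with 15 groups and 30 residual degrees of freedom was fitted per assay. The comparisons were each dose against 0 mg on each day, each dose against 0 mg as the mean of the days, days 3 and 12 against day 1 at 0 mg, and the dose-by-day interaction (8 degrees of freedom). Benjamini-Hochberg adjusted p under 0.05 was called, within each comparison. Lists of miRNAs (leukocyte, epithelial, muscle, erythroid, fibroblast, endothelial, stress and neuronal miRNAs, the let-7 family and the miR-17-92 clusters) fixed at the same time as the comparisons were tested with camera at a preset correlation of 0.01, adjusted over 10 lists and 18 comparisons.

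The reference table at hand (assembly ARS-UCD2.0) matched 0 of the 24616 gene identifiers in the mRNA files, so genes are not named, the mRNA gene and cell type lists were not tested, and at most 2 identifiers per direction are printed. The named miRNAs of a comparison are the 6 largest increases and 6 largest decreases among those with an adjusted p under 0.05 whose libraries did not overlap (for means of days, the same sign on all days), plus up to 4 called members of each list; where none passed, the 2 smallest p are given as not passing. Members of families with near-identical sequence, such as miR-196a and miR-196b or the miR-2284 and miR-2285 families, are uncertain because reads can be shared.

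Alternatives chosen before the data were examined were DESeq2 1.42.0 on recovered reads (rounded to whole numbers for miRNA), relative log expression size factors, no low-count filter, the compared groups' libraries alone, the replicate number as a block, and each library left out in turn. Alternatives added after the data were seen were edgeR 4.0.16 on recovered reads, pseudocounts of 2 (mRNA) and 5 (miRNA), no further scaling, sample quality weights, the mRNA fit without 6 libraries of TMM factor under 0.9, and the miRNA fit without its shallowest library. The closing section gives their effect.

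The main fit was tested on simulated data: negative binomial counts for the real features and depths, with known changes at 50 mg. For the miRNA comparison of 50 mg with 0 mg as the mean of days (267 miRNAs), 75% of the 2-fold and 95% of the 4-fold changes were recovered, with 3 false calls. On day 1 alone, 25% of the 2-fold and 70% of the 4-fold changes were recovered, with 0 false calls. For mRNA (15003 genes), 62% and 92% were recovered in the mean of days and 26% and 70% on day 1, with 7 and 8 false calls. The simulation drew each feature independently, so it lacks variation that the features of a library share. Such variation was large in the mRNA libraries, whose first principal component held 58.7% of the variance. The false calls thus do not show how many arise in the real data.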

Results

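The response of the calf ileum to allicin was measured at 4 doses and 3 times in the same loops by mRNA and small RNA sequencing, with 3 loops per dose and day. The mRNA libraries held 9133789 to 16145200 reads, and the small RNA libraries 480657 to 2097846 except for 30398 in 50 mg day 3 replicate 3. The 10 most abundant miRNAs took 70.35% to 83.23% of a library's reads.

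Over the days, 500 mg of allicin raised 29 miRNAs and lowered 24 of the 267 tested. miR-423-5p rose from 408.4 ± 207 to 950.4 ± 294 CPM (SD, n = 9; log2 fold change 1.56, adjusted p = 0.000436 by limma, above the control mean in 9 of 9 loops). miR-6529a rose from 77.05 ± 17.8 to 174.1 ± 45.5 CPM (1.35, adjusted p = 1.82e-06 by limma, 9 of 9 loops). miR-429, a member of the epithelial miR-200 family, rose from 478.7 ± 138 to 1012 ± 367 CPM. miR-132, miR-411c-5p and miR-224 rose by 1.15, 1.07 and 0.97 on the log2 scale. miR-2887 fell from 45.74 ± 29.7 to 0.8135 ± 1.21 CPM and miR-2904 from 12.7 ± 8.86 to 0.8285 ± 1.3 CPM, each below the control mean in 9 of 9 loops. Their fitted log2 fold changes, -4.50 and -2.76, depend on the pseudocount, since several treated libraries held 0 reads of them. miR-196a, which lies beside HOX genes, fell from 204.2 ± 46.1 to 78.68 ± 61.1 CPM. miR-2285aa, miR-96 and miR-193a-3p had log2 fold changes of -1.03, -1 and -0.93. Of the 53 called, 52 had the same sign on each day. Without the low-count filter, 17 rose and 11 fell. With no scaling beyond the deposited CPM, 13 rose and 47 fell, and the median miRNA lay at -0.201 on the log2 scale.

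**Figure D1:**
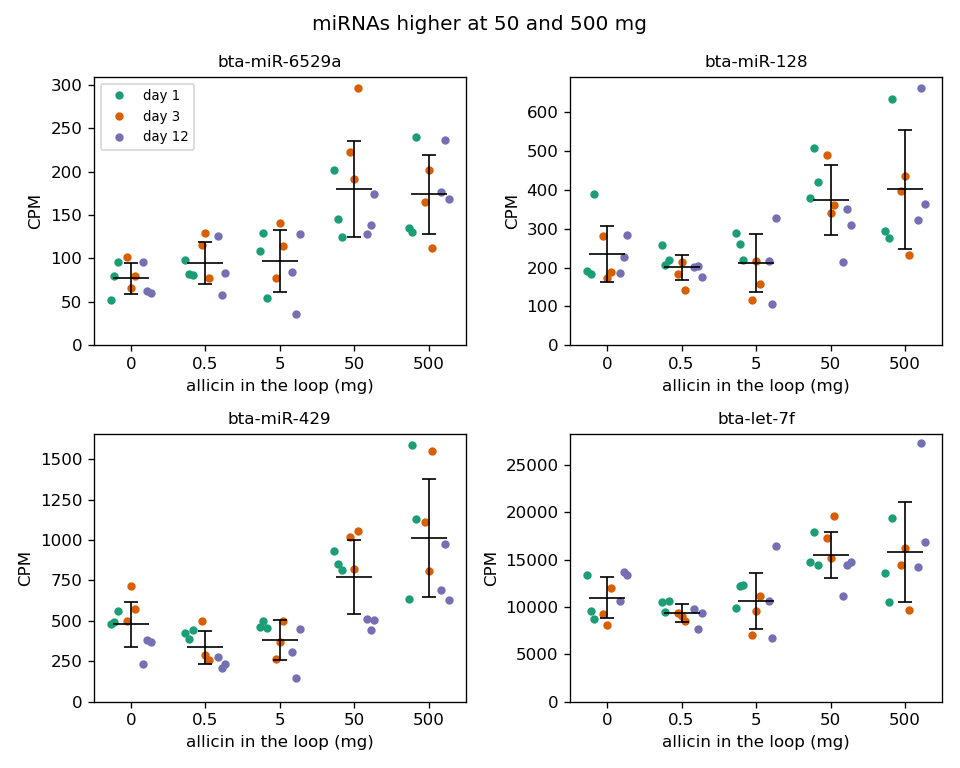
CPM of miR-6529a, miR-128, miR-429 and let-7f in each small RNA library (points, coloured by day) against the dose of allicin in mg; bars show the mean and SD of 9 libraries per dose. The mean of miR-6529a was 77.05 CPM at 0 mg, 180.2 at 50 mg and 174.1 at 500 mg.

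Members of the lists went both ways at 500 mg. Of 12 leukocyte miRNAs, the myeloid miR-223 rose from 131.4 ± 47.8 to 229.4 ± 119 CPM and miR-142-3p, a miRNA of blood cells, fell from 2569 ± 575 to 1519 ± 809 CPM. In the let-7 family of 9, let-7f rose by 0.68 and let-7d by 0.27 on the log2 scale. In the miR-17-92 clusters of 11, miR-92a rose by 0.67, while miR-93, miR-20b and miR-106a had changes of -0.29, -0.79 and -0.92; adjusted over the list alone, 1 rose and 4 fell. The smooth muscle miRNA miR-143 rose from 248900 ± 45200 to 333600 ± 82800 CPM, the only call among 6 tested muscle miRNAs (2 adjusted over the list alone). Of 8 fibroblast miRNAs, miR-127 rose by 0.67, and miR-29c and miR-29b had changes of -0.49 and -0.65. Of 6 endothelial miRNAs, miR-222 and miR-221 rose by 0.70 and 0.39, and miR-10a and miR-10b had changes of -0.72 and -0.51. miR-429 was the only call among 9 epithelial miRNAs, miR-132 among 6 stress miRNAs (2 adjusted over the list alone), and miR-128 (0.94) among 4 neuronal miRNAs. None of 3 erythroid miRNAs was called (median log2 fold change -0.13). No list as a whole was called in the mean of days; the smallest adjusted p was 0.159, for the miR-17-92 clusters (camera).

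**Figure D2:**
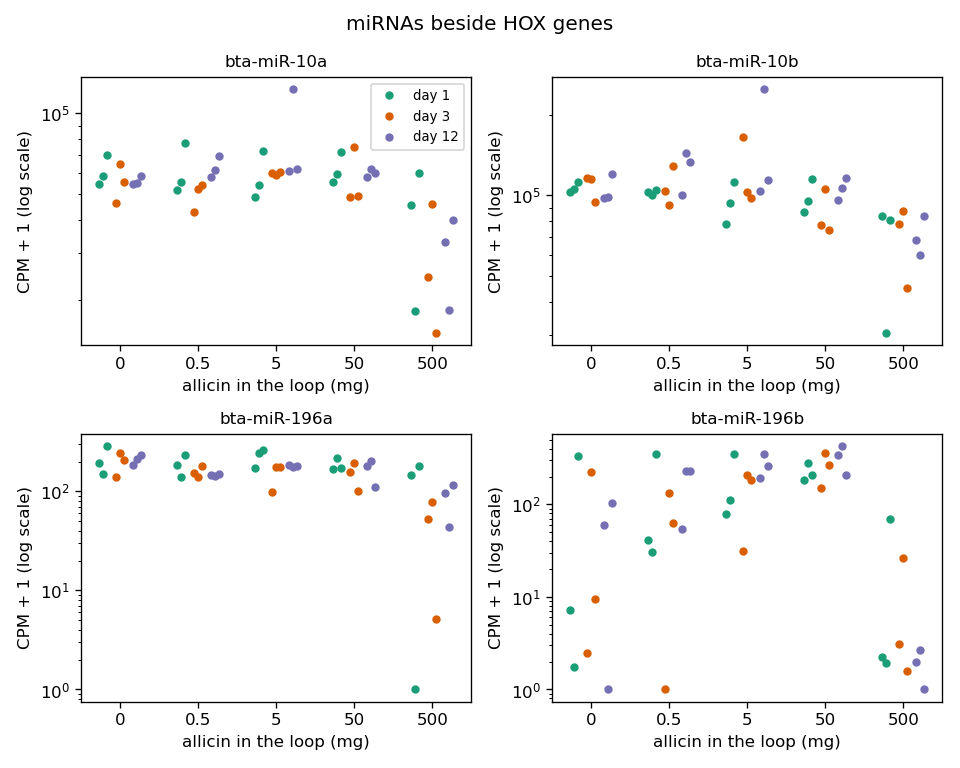
CPM plus 1 of miR-10a, miR-10b, miR-196a and miR-196b in each small RNA library (points, coloured by day, log axis) against the dose of allicin in mg. Means of miR-196b were 81.55 CPM at 0 mg, 269.3 at 50 mg and 11.35 at 500 mg, with controls spread over the axis.

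By day, 500 mg called 14 miRNAs on day 1 (9 higher, 5 lower), 8 on day 3 (5 higher, 3 lower) and 7 on day 12 (5 higher, 2 lower). miR-6529a rose on each day, by 1.40, 1.22 and 1.43 on the log2 scale, and miR-429 by 1.31, 1.21 and 1.23. miR-2887 fell from 18.21 to 0.7267, from 78.55 to 0.5854 and from 40.47 to 1.128 CPM. On day 1, miR-423-5p (2.05), miR-423-3p (0.97), miR-222 (0.73) and let-7f (0.72) also rose. miR-2904 fell from 15.55 to 0.1573 CPM, and miR-1271 (-1.40), miR-142-3p (-1.14) and miR-16a (-0.78) fell. On day 3, miR-411c-5p (1.5), miR-128 (1) and let-7f (0.73) rose, and miR-2284b (-0.97) and miR-2284x (-0.77) fell. On day 12, miR-21-3p (0.95), miR-222 (0.85) and miR-92a (0.77) rose and miR-101 (-0.55) fell. The miR-17-92 clusters were lower as a list on day 1 (median -0.74, adjusted p = 0.0189 by camera; adjusted p = 0.992 with an estimated correlation), although its single call over all miRNAs, miR-92a, rose. In the same comparison the epithelial miRNAs had a median of 0.70 (8 of 9 above 0, adjusted p = 0.0651) and the leukocyte miRNAs one of -0.38 (3 of 12 above 0, adjusted p = 0.159), neither passing. In list tests added after the data were seen, without 500 mg replicate 2 the medians were -0.18 (adjusted p = 0.608), 0.24 (adjusted p = 0.766) and -0.04 (adjusted p = 0.97), so the list changes of day 1 depend on this library. It scored highest of all on the second principal component of both assays (14.6 against 5.29 and 2.55 of the other 500 mg loops in miRNA, 120.51 against 3.4 and -30.11 in mRNA). The miR-17-92 call was also lost without 0 mg replicate 3 (adjusted p = 0.228) or 500 mg replicate 1 (adjusted p = 0.0505). The epithelial list passed without 0 mg replicates 1 or 2 or 500 mg replicates 1 or 3, and the leukocyte list without 500 mg replicate 1.

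With the compared groups alone, 500 mg called 0 miRNAs on day 1, 5 on day 3 (4 higher, 1 lower) and 7 on day 12, and without the filter 7, 2 and 2. edgeR called 20, 15 and 8, DESeq2 25, 18 and 21, and quality weights 29, 44 and 27. Without further scaling, 3 miRNAs were called on day 1 and 3 on day 3, all lower, and 3 on day 12 (2 higher, 1 lower). These daily counts also moved with single libraries. On day 1, 3, 2 and 9 were called without 0 mg replicates 1, 2 and 3, 0 without 500 mg replicate 2 and 26 without 500 mg replicate 3. On day 3, 1, 3 and 1 were called without 0 mg replicates 1, 2 and 3, and 3, 2 and 5 without 500 mg replicates 1, 2 and 3. On day 12, 2, 1 and 0 were called without 0 mg replicates 1, 2 and 3, 0 without 500 mg replicate 1 and 3 without 500 mg replicate 3.

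At 50 mg, 16 miRNAs rose and 15 fell over the days. miR-6529a rose to 180.2 ± 55.5 CPM (log2 fold change 1.35, adjusted p = 3.46e-06 by limma, 9 of 9 loops), miR-423-5p to 831.1 ± 217, miR-2478 to 140.3 ± 67.4, miR-128 to 374.6 ± 90.2 and miR-429 to 772 ± 230 CPM. miR-196b rose from 81.55 ± 119 to 269.3 ± 92.2 CPM (4.02 ± 1 SE), but was not called against 0.5 mg (2.11, adjusted p = 0.176 by limma) or 5 mg (0.73, adjusted p = 0.673 by limma). miR-2904 (-1.72), miR-96 (-1.46), miR-190a (-1.25), miR-2285aa (-1.07), miR-193a-3p (-1.02) and miR-149-5p (-0.75) fell. Their 0 mg means ran from 12.7 to 73.84 CPM, while 1 read of 50 mg day 3 replicate 3 was worth 32.9 CPM, so that library resolves them poorly. Without it, 32 miRNAs were called over the days, among them 23 of the 31. Among list members, let-7f (0.67), let-7d (0.28), miR-92a (0.57) and miR-222 (0.60) rose, and miR-29c (-0.43) and the hypoxia-responsive miR-210 (-0.45) fell. No list was called; the smallest adjusted p was 0.144, for the let-7 family (camera). The count was 18 without 50 mg day 1 replicate 3, 20 without 0 mg day 3 replicate 1 or replicate 3, and 48 without 50 mg day 3 replicate 1. Without further scaling, 6 rose and 31 fell, with the median miRNA at -0.248.

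On day 1, 50 mg raised miR-6529a (1.31), miR-128 (1.12), miR-423-3p (0.91), let-7f (0.85), miR-92a (0.79) and miR-222 (0.76), and lowered miR-101 (-0.58), which made 7 calls. The let-7 family was higher as a list (median 0.38, adjusted p = 0.0141 by camera; adjusted p = 0.992 with an estimated correlation), but not without 0 mg replicate 3 (adjusted p = 0.111) or 50 mg replicate 2 (adjusted p = 0.149). With the compared groups alone there were 13 calls, by DESeq2 14, with quality weights 45, and without the filter 4. Without 0 mg replicates 1, 2 and 3 there were 2, 0 and 3 calls, and without 50 mg replicates 1 or 3 there were 0.

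On day 3, 11 miRNAs were called at 50 mg. miR-6529a (1.57), miR-2478 (1.39), miR-128 (0.95), let-7f (0.89) and miR-92a (0.80) rose, and miR-96 (-3.15), miR-1388-3p (-2.33), miR-2284y (-2.31), miR-2284b (-0.91) and miR-210 (-0.82) fell, while the median miRNA lay at -0.199. With the compared groups alone 2 were called, and by edgeR or DESeq2 4. One read of 50 mg replicate 3 was worth 32.9 CPM, and without it 0 miRNAs were called; 50 and 51 were called without 50 mg replicates 1 and 2, and 2, 4 and 5 without 0 mg replicates 1, 2 and 3.

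On day 12, 50 mg called 0 miRNAs by limma, edgeR or DESeq2, with 18 at an unadjusted p under 0.05 (1 without the filter, 10 with quality weights). miR-6529a (1.18, adjusted p = 0.112 by limma) and miR-101 (-0.57, adjusted p = 0.112 by limma) had the smallest p and did not pass.

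Both doses were compared with the same 0 mg loops. They shared 14 called increases and 10 called decreases, against 1.74 and 1.35 for independent lists and 0 in simulations of unchanged groups. Their log2 fold changes had a covariance of 0.127 across miRNAs, against 0.0351 in those simulations, and a correlation of 0.42 against 0.45. The simulations drew each miRNA independently, whereas real miRNAs are not independent replicates, so they cannot weigh variation that miRNAs share. With separate 0 mg loops as controls for each dose, the correlation averaged 0.33 over the ways of dividing the loops (0.17 to 0.51). The covariance averaged 0.104. In a comparison of 500 with 50 mg added after the data were seen, miR-2887 (-3.20), miR-196b (-6.05) and miR-10a (-0.94) were lower at 500 mg, and no other miRNA was called.

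At 0.5 and 5 mg, 0 miRNAs were called on any day or over the days by limma, edgeR or DESeq2. Quality weights called 2 at 5 mg on day 1, and no filter gave 1 and 1 on day 1 and 2 and 1 on day 3. At an unadjusted p under 0.05 there were 3, 3 and 6 at 0.5 mg and 5, 1 and 20 at 5 mg on days 1, 3 and 12, and 5 and 2 over the days. Apart from the 20, these are smaller shares of the 267 miRNAs than the 0.05 expected with no change. The absence of calls thus does not show an absence of change. The smallest p over the days, none passing, belonged to miR-2284z (-0.39) and miR-221 (-0.31) at 0.5 mg and miR-196b (3.29) and miR-365-3p (0.66) at 5 mg. On day 1 they belonged to miR-423-3p (0.52 and 0.51) and miR-19a (-0.83 at both doses). On day 3 they belonged to miR-2284z (-0.57) and miR-221 (-0.46) at 0.5 mg and miR-502b (1.09) and miR-495 (-1.45) at 5 mg. On day 12 they belonged to miR-423-3p (-0.59) and let-7a-5p (-0.48) at 0.5 mg and miR-423-3p (-0.76) and miR-181a (-0.69) at 5 mg. On day 12, 6 and 1 were called at 5 mg without 5 mg replicates 1 and 3.

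Some lists were called at these doses by camera, though no member was, over all miRNAs or adjusted over the list alone, and none of these calls held with an estimated correlation. With the replicate number as a block, the miR-17-92 clusters also passed as lower at 0.5 mg on day 1 (adjusted p = 0.0384 by camera, 0.0651 without the block). At 0.5 mg the epithelial miRNAs were lower on day 3 (median -0.46, adjusted p = 0.00177; adjusted p = 0.992 with an estimated correlation) and over the days (-0.30, adjusted p = 0.0149 and 0.992). The muscle miRNAs were higher on day 3 (0.60) and over the days (0.37), each with adjusted p = 0.00448 (adjusted p = 0.986 with an estimated correlation). Without 0.5 mg day 3 replicate 2, adjusted p was 0.368 and 0.187 for the epithelial miRNAs and 0.501 and 0.0809 for the muscle miRNAs, so these calls depend on that library. Without 0 mg day 3 replicate 2 the epithelial calls were also lost (adjusted p = 0.23 and 0.159). The let-7 family was lower on day 12 (-0.19, adjusted p = 0.00448; adjusted p = 0.986 with an estimated correlation), but not without 0 mg replicate 2 or 0.5 mg replicates 1 or 3 (adjusted p = 0.261, 0.115 and 0.0898). At 5 mg the epithelial miRNAs were lower on day 3 (-0.38, adjusted p = 0.0393; adjusted p = 0.992 with an estimated correlation), but not without 0 mg replicates 2 or 3 or 5 mg replicate 2 (adjusted p = 0.743, 0.0643 and 0.559). The muscle miRNAs had a median of 0.39 there (6 of 6 above 0) without passing (adjusted p = 0.0689). These day 3 comparisons share their 3 control loops with each other and with day 3 against day 1.

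Without allicin, 0 miRNAs were called between day 3 or day 12 and day 1 by limma, edgeR or DESeq2 (8 and 10 at an unadjusted p under 0.05). Both are smaller shares of the 267 miRNAs than the 0.05 expected with no change, so this does not show an absence of change. Without the filter 2 and 1 were called, with the compared groups alone 1 on day 3, and with quality weights 4 on day 12. The smallest p, none passing, belonged to miR-2887 (2.16) and miR-223 (1.04) on day 3 and to miR-21-3p (-1.01) and miR-147 (-1.16) on day 12. The epithelial list was higher on day 3 (median 0.36, adjusted p = 0.0393 by camera; adjusted p = 0.992 with an estimated correlation) and the let-7 family on day 12 (0.25, adjusted p = 0.00603; adjusted p = 0.986 with an estimated correlation). The first was lost without day 1 replicate 3 or day 3 replicates 2 or 3 (adjusted p = 0.228, 0.687 and 0.0643), and the second without day 1 replicate 3 or day 12 replicate 2 (adjusted p = 0.149 and 0.291). The dose-by-day interaction called 0 miRNAs by limma, edgeR and DESeq2 (4 at an unadjusted p under 0.05), and 1 with quality weights or without the filter. With 3 loops per group, this does not exclude dose effects that differ between days.

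The genes of the mRNA libraries could not be named. Over the days, 500 mg called 5609 of 15107 genes (2441 higher, 3168 lower) and 50 mg called 4159 (1872 higher, 2287 lower). The majority direction depended on the analysis. Relative log expression factors gave 2893 higher and 2617 lower at 500 mg and 2152 and 1676 at 50 mg, and no further scaling gave 2962 and 2041, and 2002 and 1273. At 500 mg DESeq2 gave 3039 higher and 2901 lower and edgeR 2070 and 3111; at 50 mg DESeq2 gave 1948 and 2570, edgeR 1046 and 2690, and no filter 1165 and 916. With the compared groups alone, 50 mg called 1790 higher and 1562 lower, and 500 mg called 0. At 500 mg, ENSBTAG00000011752 rose from 54.2 ± 47 to 220 ± 134 CPM (log2 fold change 2.46, adjusted p = 0.0135 by limma, 9 of 9 loops) and ENSBTAG00000006434 from 27.9 ± 26.9 to 95.5 ± 62.7 CPM. ENSBTAG00000005128 fell from 421 ± 185 to 201 ± 144 CPM and ENSBTAG00000035183 from 12.6 ± 6.63 to 4.44 ± 3.04 CPM. At 0.5 and 5 mg, 0 were called over the days (143 and 724 at an unadjusted p under 0.05; edgeR 0 at both, DESeq2 2 and 0, quality weights 0 and 6064). The 500 mg count was 2856 without 500 mg day 1 replicate 2, 315 without 0 mg day 3 replicate 1 and 424 without 0 mg day 12 replicate 3. The 50 mg count was 4, 1609 and 23 without 0 mg day 1 replicates 1, 2 and 3, and 1478 and 0 without 50 mg day 1 replicates 2 and 3. It was 1 and 7500 without 0 mg day 3 replicates 1 and 2, and 9 and 2262 without 50 mg day 3 replicates 1 and 2. It was 2190, 6430 and 0 without 0 mg day 12 replicates 1, 2 and 3, and 8, 5 and 2460 without 50 mg day 12 replicates 1, 2 and 3.

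On day 1, 0 genes were called at any dose, with 15, 62, 40 and 414 at an unadjusted p under 0.05 from 0.5 to 500 mg. These are smaller shares of the 15107 genes than the 0.05 expected with no change, so the absence of calls does not show an absence of change. Of the other tests, edgeR called 0 and DESeq2 1 at each dose, and quality weights 0, 161, 6 and 1576. On day 3, 1 gene was called at 500 mg and 0 at 0.5, 5 and 50 mg (from 0.5 to 500 mg, 1384, 2314, 4963 and 5362 at an unadjusted p under 0.05; edgeR 0, 0, 0 and 1, DESeq2 15, 27, 1639 and 1952, quality weights 0 at each dose). The 1952 of DESeq2 at 500 mg were 503 higher and 1449 lower. Without 0 mg day 3 replicate 2, 1, 3415, 6339 and 6903 genes were called from 0.5 to 500 mg. Without 0 mg replicate 3, 5, 50 and 500 mg called 1, 4 and 2. At 500 mg there were 0 without 0 mg replicate 1 or 500 mg replicate 2, and 2 without 500 mg replicate 3.

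On day 12, 50 mg called 5493 genes (2420 higher, 3073 lower) and 500 mg 29 (17 higher, 12 lower), and 0.5 and 5 mg called 0 (from 0.5 to 500 mg, 24, 1035, 7392 and 5351 at an unadjusted p under 0.05; edgeR 0, 0, 5117 and 25, DESeq2 1, 5, 5801 and 398). Quality weights gave 13763, 11747, 12009 and 10137, so the absence of calls at 0.5 and 5 mg did not hold with unequal weights. At 0.5 mg, however, each fit with 1 library left out called 0. There, 0 mg replicates 1 and 3 and 0.5 mg replicates 1 and 2 had TMM factors under 0.9. Whether the weighted counts rest on few libraries was not tested. The calls of DESeq2 were 3012 higher and 2789 lower at 50 mg, and 233 higher and 165 lower at 500 mg. At 50 mg the majority rose with relative log expression factors (2796 higher, 2254 lower), without the filter (2308 and 2092) and without further scaling (3157 and 1557), and with the compared groups alone 0 were called at 50 and 500 mg. The 50 mg count was 2771 and 0 without 0 mg replicates 1 and 3, and 0, 3199 and 2882 without 50 mg replicates 1, 2 and 3. The 500 mg count was 13, 4335 and 5 without 0 mg replicates 1, 2 and 3, and 10 and 1 without 500 mg replicates 2 and 3. At 5 mg, 4445 were called without 5 mg replicate 2.

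Without allicin, day 12 differed from day 1 in 4614 genes (2564 higher, 2050 lower) and day 3 in 3, all higher (7110 and 5095 at an unadjusted p under 0.05; edgeR 4177 and 7, DESeq2 5154 and 1398, quality weights 12685 and 0). The 1398 of DESeq2 on day 3 were 1206 higher and 192 lower. With relative log expression factors 1800 were higher and 2311 lower on day 12, without the filter 1291 and 1684, and without further scaling 1096 and 2663. The day 12 count was 0 without any 1 of the day 1 loops or without day 12 replicates 1 or 3. The day 3 count was 0 without any 1 of the day 1 loops or day 3 replicate 1, 6725 without day 3 replicate 2 and 7 without day 3 replicate 3. The interaction called 0 genes by limma and edgeR and 19 by DESeq2, with 519 at an unadjusted p under 0.05, but 12363 with quality weights.

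The first principal component of the mRNA libraries held 58.7% of the variance. The TMM factor was under 0.9 in 6 libraries: 0 mg day 3 replicate 1, 0 mg day 12 replicates 1 and 3, 0.5 mg day 12 replicates 1 and 2, and 5 mg day 12 replicate 2. A fit without these 6 keeps only 1 of the 0 mg day 12 loops, replicate 2. It thus cannot tell whether the calls on day 12 and over the days rest on the 6 libraries, and no conclusion is drawn from its counts.

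**Figure D3:**
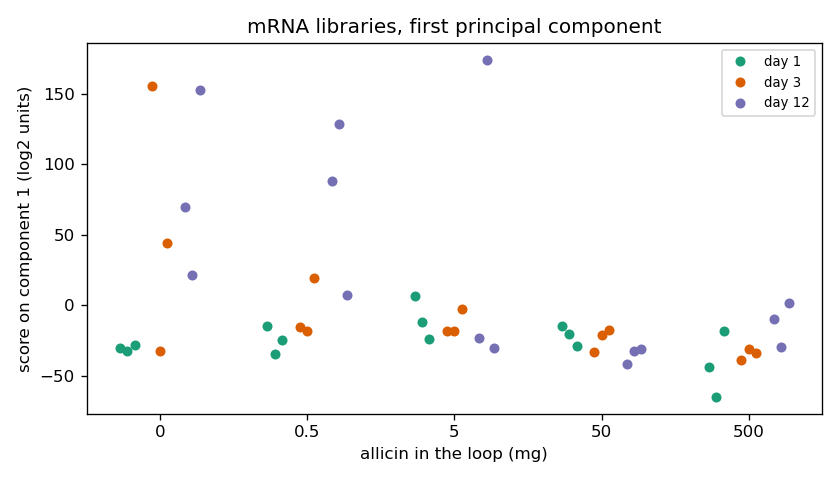
Score of each mRNA library on the first principal component (log2 units) against the dose of allicin in mg, coloured by day. Libraries of 50 and 500 mg lay at or below 1.75, and the highest score, 174.19, was that of 5 mg day 12 replicate 2.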

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

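The DESeq2, relative log expression, filter, compared-groups, block and left-out-library alternatives were planned; edgeR, the other pseudocounts, no further scaling, quality weights, the list tests with 1 library left out and the fits without the low-TMM or low-depth libraries were chosen after the data were seen. No named miRNA reversed its sign, but the majority direction of several counts turned with the scaling, the filter, the test or the libraries fitted, as given below. The cause of each move was not tested. The mRNA gene lists were not run, because no identifier matched the reference.

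DESeq2 called, in mRNA, 1 at each dose on day 1, 15, 27, 1639 and 1952 on day 3 from 0.5 to 500 mg, 1, 5 and 398 on day 12 at 0.5, 5 and 500 mg, 2 over the days at 0.5 mg, 1398 for day 3 against day 1 and 19 for the interaction. In miRNA it called 14 and 25 on day 1 and 4 and 18 on day 3 at 50 and 500 mg, and 21 at 500 mg on day 12. edgeR called 7 genes for day 3 against day 1, and 4 and 15 miRNAs on day 3 at 50 and 500 mg; over the days it called 3736 and 5181 genes and 27 and 77 miRNAs at 50 and 500 mg. List calls fell to 0 of 180 with an estimated correlation (6 at an unadjusted p under 0.05) and were 11 with the block and 10 with relative log expression factors.

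With the compared groups' libraries alone, mRNA calls were 0 at 50 mg on day 12, 0 at 500 mg on days 3 and 12 and over the days, 2649 for day 12 and 0 for day 3 against day 1. miRNA calls were 13 and 0 on day 1 and 2 and 5 on day 3 at 50 and 500 mg, and 1 for day 3 against day 1. Without the 6 libraries of TMM factor under 0.9, mRNA calls were 4 and 0 on day 3, 0 and 0 on day 12 and 2 and 625 over the days at 50 and 500 mg, and 0 for both days against day 1. That mRNA fit kept only 1 of the 0 mg day 12 loops and lacked 0 mg day 3 replicate 1. Its counts on day 12, over the days and for day 12 against day 1 thus rest on 1 control library for day 12. They cannot show whether the calls depend on the 6 libraries, and no conclusion is drawn from them. Without the shallowest library, miRNA calls on day 3 were 0 at 50 mg and 13 at 500 mg.

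Without further scaling, mRNA calls were 0 at 500 mg on day 3 and 0 for day 3 against day 1. miRNA calls were 0 and 3 on day 1 and 3 and 3 on day 3 at 50 and 500 mg, and 3 at 500 mg on day 12. The direction moved too: 3157 genes rose and 1557 fell at 50 mg on day 12 (median shift 0.322), 20 and 3 at 500 mg on day 12, 2962 and 2041 over the days at 500 mg, 2002 and 1273 at 50 mg, and 1096 and 2663 for day 12 against day 1 (median shift -0.325). With relative log expression factors, 1 gene was called for day 3 against day 1 and 5 miRNAs at 500 mg on day 3 (2 higher, 3 lower). They gave 2796 higher and 2254 lower genes at 50 mg on day 12, 2152 and 1676 over the days, 2893 and 2617 over the days at 500 mg, and 1800 and 2311 for day 12 against day 1. The majority also turned in fits that kept TMM, computed again from the genes or libraries fitted. Without the filter, 1165 genes rose and 916 fell over the days at 50 mg, 2308 and 2092 on day 12 at 50 mg, and 1291 and 1684 for day 12 against day 1. With the compared groups alone, 1790 rose and 1562 fell over the days at 50 mg, and with quality weights 4672 and 5465 on day 12 at 500 mg. DESeq2, which has factors of its own, gave 3039 and 2901 over the days at 500 mg and 3012 and 2789 on day 12 at 50 mg.

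Without the filter, mRNA calls were 2 and 3 on day 1 at 5 and 500 mg, 2 at 500 mg on day 3, 1 at 5 mg on day 12, 1 and 2081 over the days at 5 and 50 mg, 5 and 2975 for days 3 and 12 against day 1, and 3 for the interaction. miRNA calls were 1, 1, 4 and 7 on day 1 and 2, 1, 7 and 2 on day 3 from 0.5 to 500 mg, 1 and 2 on day 12 at 50 and 500 mg, 28 over the days at 500 mg, 2 and 1 for days 3 and 12 against day 1, and 1 for the interaction. With quality weights, mRNA calls were 161, 6 and 1576 on day 1 from 5 to 500 mg, 0 at 500 mg on day 3, 13763, 11747, 12009 and 10137 on day 12 from 0.5 to 500 mg, 6064 and 7520 over the days at 5 and 50 mg, 0 and 12685 for days 3 and 12 against day 1, and 12363 for the interaction. miRNA calls were 2, 45 and 29 on day 1 from 5 to 500 mg, 44 at 500 mg on day 3, 10 and 27 on day 12 at 50 and 500 mg, 74 over the days at 50 mg, 4 for day 12 against day 1 and 1 for the interaction. The other pseudocounts kept each count within 1.5 times.

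The replicate numbers were not taken to pair the libraries, because the labels name no shared animal and not every same-number pair correlated above 0.1 within days. Every pair did so in 2 of 12 mRNA and 5 of 12 miRNA comparisons with 0 mg. Among them were 50 and 500 mg on day 12 in mRNA and 500 mg on day 1 in miRNA. Same-number correlations averaged 0.2 in mRNA (-0.81 to 0.92) and 0.19 in miRNA (-0.12 to 0.59), against -0.1 and -0.09 for other numbers. In each assay, 40 of 45 libraries correlated best with their own number, which points to a shared source. If the numbers mark one, the main tests leave that pairing out and only the block fits use it. With the number as a block, mRNA calls were 20 on day 3 and 70 on day 12 at 500 mg, and miRNA calls 12 and 22 on day 1 at 50 and 500 mg (10 higher and 12 lower at 500 mg).

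With 1 library left out at a time, mRNA calls ranged over 0 to 1 (0.5 mg day 3), 0 to 3415 and 0 to 4445 (5 mg days 3 and 12), 0 to 6339, 0 to 7101 and 0 to 7500 (50 mg days 3, 12 and over the days), 0 to 6903, 1 to 4335 and 315 to 8080 (500 mg, the same), and 0 to 6725 and 0 to 6749 (days 3 and 12 against day 1). miRNA calls ranged over 0 to 6 (5 mg day 12), 0 to 5, 0 to 51 and 18 to 48 (50 mg days 1, 3 and over the days), and 0 to 26, 1 to 5, 0 to 5 and 37 to 65 (500 mg days 1, 3, 12 and over the days). List calls ranged over 4 to 19, and each of the 10 was lost without at least 1 library. Of 1296 values of named miRNAs, 999 kept their side of the threshold, 294 lost it and 3 gained it. Of 114 under each other setting, 72 (no filter) to 112 (block) kept it.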

Other observations

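Chosen after results were seen were the tests of 1 low-depth library, of handling that follows the dose, of reads shared by miR-196a and miR-196b, of the size ratios, of the HOX-neighbour pairs of unlike sequence and of the depths of the 6 libraries apart, the intervals of r, the other control doses and the relations with the second component.

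Within groups, the second component of the mRNA libraries was related most strongly to the share of the 10 most abundant genes (r 0.76, p = 1e-05, adjusted p = 9.3e-05; rho 0.64, p = 1e-05; r 0.75 without the 2 farthest libraries; 28 relations, 45 libraries, permutation tests whose smallest p is 1e-05). Of the cell type miRNAs of the matched small RNA libraries, the leukocyte list had r -0.61 (p = 1e-04, adjusted p = 0.00051; rho -0.36, p = 0.016; r -0.41 without 2). The muscle list had r 0.56 (p = 0.00011, adjusted p = 0.00051; rho 0.43, p = 0.0034; r 0.31 without 2). The epithelial list had r 0.57 (p = 0.00052, adjusted p = 0.0016) but rho 0.18 (p = 0.24), with r 0.47 without 2. By r, the endothelial, fibroblast, neuronal and erythroid lists did not pass (r -0.08, -0.04, 0.05 and 0.21, adjusted p 0.94, 0.94, 0.94 and 0.32). The erythroid list, however, had the largest rho in size of the cell type lists (0.47, p = 0.0016 by permutation), with r 0.37 without 2. Lists of no cell type were related as strongly, the miR-17-92 clusters with r -0.62 (p = 5e-05, adjusted p = 0.00035; rho -0.48, p = 0.00086; r -0.32 without 2) and the stress miRNAs with r 0.56 (p = 0.00047, adjusted p = 0.0016; rho 0.43, p = 0.0031; r 0.44 without 2).

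miRNAs changed at 50 and 500 mg, and none was called at 0.5 or 5 mg by the main limma fit, edgeR or DESeq2. Quality weights, no filter and left-out libraries called a few there, as given above, and the absence of calls does not show an absence of change. With log2 depth as a covariate, 53 of the 53 miRNAs called at 500 mg stayed called (median size ratio 1). The slope was fitted over all libraries, with the 1 of 30398 reads at 50 mg far from the rest, so this fit alone does not exclude depth. The 0 mg libraries held 624891 to 1296509 reads and the 500 mg libraries 587083 to 2097846, so their depths overlapped. With the 10 most abundant taken out, 36 of the other 49 stayed called (73.5%, between the bounds of 50% and 80% first set), but 386 miRNAs instead of 267 then passed the filter. Over the same 257 miRNAs 45 stayed called (91.8%), all 49 kept their sign and the median size ratio was 1.02 (quartiles 1 to 1.04). TMM takes up a shift common to the other miRNAs of a library, so these signs and sizes could hardly change. The test thus cannot decide whether a few abundant miRNAs were a source of the changes. Without further scaling, the split at 500 mg went from 29 higher and 24 lower to 13 and 47. Without the low-depth library, 23 of the 31 called at 50 mg stayed called (74.2%), so that single calls depend on it, but 32 were called at 50 mg and 76 at 500 mg and 31 of 31 kept their sign (median size ratio 0.95), which argues against it as the only source; a criterion on size ratios had been tried and dropped before. Unequal handling or batches that follow the dose cannot be told apart from the dose, since the labels give no batch; the median ratio of the 500 to the 50 mg change, 1.09, decides nothing, being taken over the 24 miRNAs called at both.

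Against 0.5 and 5 mg as controls, 28 and 14 miRNAs were called at 50 mg, and 42 and 38 at 500 mg. The mean of miR-2887 was 45.74, 74.11, 50.38, 20.84 and 0.8135 CPM from 0 to 500 mg.

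miR-196a and miR-10a were lower at 500 mg, as was miR-196b against 50 mg but not, as a call, against 0 mg (-2.03, adjusted p = 0.155 by limma). The summed CPM of miR-196a and miR-196b also fell (-2.27 ± 0.58 SE; 90.03 ± 77.3 against 285.7 ± 160 CPM), which argues against shared reads as the whole cause, and the mean change of the 3 was -1.63 with depth as a covariate and -1.65 without it. A hypothesis is that loops lay at different positions along the intestine, as miR-10a, miR-10b, miR-196a and miR-196b lie beside HOX genes: their mean correlation between loops of 1 group was 0.46, but this includes pairs of similar sequence, which random sets lack. Over the pairs of unlike sequence alone it was 0.4, and 0.33 in the 36 loops of 0 to 50 mg, above the 95th percentiles of 9666 random sets (0.24 and 0.23), so position may contribute, as may any other source of joint variation. An effect of the dose stays open.

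The 6 mRNA libraries with low TMM factors stood apart on the first component, which followed the TMM factor (r -0.98, p = 1e-05, the smallest the permutations can give) and the genes detected (r -0.88). The component, the factor and the genes detected come from the same values, so these relations are not independent evidence. The component's r with depth within groups was -0.21 (95% interval -0.53 to 0.16), which alone leaves depth open. Of the 6, 4 had depths between the quartiles of all libraries. The 2 with the highest scores lay below the lower quartile of 10939234 reads. They were 5 mg day 12 replicate 2 (score 174.19, 9133789 reads, the fewest of all) and 0 mg day 3 replicate 1 (155.6, 10319069 reads). Low depth thus does not account for the 4. Of the libraries shallower than 0 mg day 3 replicate 1, only 5 mg day 12 replicate 2 stood apart. Examples are 0.5 mg day 3 replicate 2 (9622534 reads, score -18.01) and 5 mg day 12 replicate 3 (10143119, -30.36). No library was shallower than 5 mg day 12 replicate 2, but 500 mg day 12 replicate 3 came near (9370661, 1.75). These values argue against low depth alone for these 2 as well. The share of the 10 most abundant genes had r -0.04 (-0.39 to 0.32), which argues against that source. For tissue make-up, the largest r with a cell type list was 0.22 (endothelial miRNAs), inside the bound of 0.3 set against it, but its interval of -0.15 to 0.53 reaches past the 0.5 set for it, so it stays undecided; a first version that took all lists had 0.54 for the miR-17-92 clusters (rho 0.44, adjusted p = 0.0016; 0.38 without 2), which is not a cell type list. An effect of dose or day on it was not tested and stays open.

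Other splits of the same libraries were counted. Over the days, 1 of 100 splits, the real one, gave as many miRNAs at 50 mg (31, highest other 1) and 1 of 100 at 500 mg (53, highest other 31). This is the smallest share that 100 splits can give. It lies under 0.05 with no adjustment over the comparisons, which makes chance alone less likely but does not exclude it. The splits moved loops freely within a day, so a source shared by loops of 1 replicate number, if there is one, stays open. In mRNA, 4 of 100 gave as many at 50 mg (4159; highest other 6037) and 3 of 100 at 500 mg (5609; highest other 6018), shares under 0.05 with no adjustment over the comparisons; as other splits called more genes than the real ones, a structure of the samples stays open as the source of these counts. With 0 calls, all 100 splits were as large: the highest others were 5454, 8139 and 4013 genes at 0.5 mg, at 5 mg and for the interaction, which point to a structure of the samples, and 1, 1 and 2 miRNAs.

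With 3 loops against 3 there are 10 splits, too few for a share under 0.05. In miRNA, 1 of 10 reached the real count at 50 and 500 mg on day 1 (7 and 14; highest other 0 for both), on day 3 (11 and 8; highest others 1 and 2) and at 500 mg on day 12 (7; 0). In mRNA, 1 of 10 did so at 50 and 500 mg on day 12 (5493 and 29; highest others 1 and 0) and for days 12 and 3 against day 1 (4614 and 3; 0 for both), and 4 of 10 at 500 mg on day 3 (1; 933). For the comparisons with 0 calls, all 10 were as large; the highest other was 8434 genes at 5 mg on day 12, which points to a structure of the samples, and at most 2 elsewhere.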
